A study of Mus musculus with 2 samples.

How the data were processed

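Single-cell RNA was measured in 2 libraries of mouse long-bone marrow, 1 from adult and 1 from old C57BL6 mice. Per the labels' protocols, blood-forming cells were depleted on an autoMACS separator, debris and dead cells were gated out by scatter and DAPI, and the sorted cells went into the 10x Chromium Next GEM 3' kit. The labels give the age group as a word only. The number of mice, their ages in months, their sex and whether marrow was pooled are not given in the sources used here.

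For each library the authors deposited a list of genes, a list of cell barcodes and a sparse matrix of raw UMI counts per gene and barcode. Per the submitters' processing notes, these deposited counts were made with Cell Ranger on the GRCm39 build, and the file headers carry the version 7.0.1. The annotation release and any filter on barcodes are not given in the sources used here. Both libraries list the same genes. The lowest total of any barcode was 500 UMIs. Gene symbols and identifiers are used as the files pair them. No genomic positions are given, because the reference annotation used here (GENCODE M21) is of another build, GRCm38. It served only for gene lengths, matched by Ensembl identifier, in a check for a length trend.

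Barcodes with fewer than 500 genes or with over 10% mitochondrial UMIs were left out. In the adult library, 1582 barcodes had too few genes and 1650 had too many mitochondrial UMIs, which left 22403 of 25635. In the old library, 1754 and 1569 were left out in the same way, which left 18975 of 22298. Scrublet was run on each library and called 0 cells at its own thresholds, so it did not work here and no doublets were removed. Removing the highest 10% of doublet scores was added as an alternative after the data were examined.

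Cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled with values limited to 10, and 50 principal components gave 15 nearest neighbours per cell. Shared neighbours were clustered by the Leiden algorithm at resolution 1, and clusters under 20 cells were joined to their nearest cluster. Each cluster was scored on 24 marker lists fixed before the data were examined, by the mean over markers of log2(CPM + 10), scaled from the lowest to the highest cluster. A cluster took the name with the best score when that score was at least 0.45, when at least 3 of its markers were found in over 10% of its cells, and when its 10 leading genes held no more markers of another class than of its own. Where the lead over the next score was under 0.1, the markers among the 10 leading genes decided or the cluster stayed unnamed. A cluster of very low UMI counts with no own marker among those genes also stayed unnamed. These naming thresholds were set after the data were examined. Names carry the ending "-like" because they rest on markers alone. CAR-like cells are those with the markers of CXCL12-abundant reticular cells, the perivascular mesenchymal cells that support blood stem cells. No cluster took the names tenocyte, adipocyte, skeletal muscle, monocyte or macrophage, dendritic cell, basophil or mast cell, eosinophil, haematopoietic stem or progenitor cell, or osteoclast.

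Within each class of at least 100 cells in both libraries, UMIs were summed per gene and library and divided by the class total and scaled in the usual way to CPM. Ratios are log2 of old over adult CPM. A gene was counted when it had at least 50 CPM and 50 UMIs in the library where it was higher, and it was called apart when its CPM differed at least 2-fold. The genes named in the text followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest ratios among genes with at least 100 CPM and 100 UMIs in each of the 3 largest non-haematopoietic classes, and 3 of each in other classes. It left out mitochondrial, ribosomal, immunoglobulin, haemoglobin, predicted and sex-linked genes, blood-cell markers and the free RNA list. It always took 10 niche genes in CAR-like cells and 8 vascular genes in endothelial-like cells. From each gene list it took up to 4 members that lay farthest in the direction of the list's median.

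The 27 gene lists, also fixed beforehand, covered haematopoietic niche factors, CAR cell identity, adipogenic genes, osteogenic genes, collagens and matrix, matrix remodelling enzymes, senescence, inflammatory cytokines, interferon response, antigen presentation, immediate early genes, heat shock, the unfolded protein response, antioxidant genes, mitochondrially encoded transcripts, oxidative phosphorylation, glycolysis and hypoxia, ribosomal proteins, cell cycle, TGF-beta and BMP signalling, Wnt and Notch signalling, complement and acute phase genes, the IGF system, endothelial vascular function, scavenging and lysosome genes, RNA of abundant blood cells that can be free in the droplets, and sex-linked transcripts. The sinusoidal and arterial marker lists, which name subtypes of endothelial cells, were also read as gene lists in the endothelial-like class. A list's median ratio over members with at least 50 UMIs was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart where its median lay below the 2.5 percentile or above the 97.5 percentile of those lists.

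Each group holds 1 library. No test across animals was possible, no p-value is given, and the difference between libraries has no replicate check. Age, mouse, day and library preparation cannot be separated. Shares carry exact Clopper-Pearson 95% intervals and ratios carry exact Poisson-based 95% intervals, and both cover counting error only. For a share of 0, the limit that 3 counts allow is given. It counts cells in named clusters only, so cells of a class that fell in a cluster of another name are not covered. RNA set free from broken cells gives UMIs in every droplet. Its level for each gene was taken as the lower of the means per cell in megakaryocyte-like and erythroid-like cells, and a gene is marked where this level could give over 30% of its UMIs in the library where it was higher. Shares of cells with a UMI were also computed after thinning each cell to 2000 UMIs.

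The counting, the intervals and the list percentiles were tested on simulated counts drawn from the class means with 200 genes changed and the members of 1 list shifted. These counts held no effect of library, cluster or gene length, so they check the arithmetic only. In each of the 4 classes, all 50 genes set at each of 3-fold, 5-fold and 10-fold were called, 0 of the 50 set at 1.5-fold were called, and 0 unchanged genes were called. The 95% interval covered the true ratio for 95.1% of 3872 genes in CAR-like cells, 95.4% of 3198 in osteolineage-like cells, 94.8% of 4342 in endothelial-like cells and 95.3% of 4111 in pericyte or smooth muscle-like cells. The clustering was run on 600 simulated cells, 300 endothelial-like and 300 pericyte or smooth muscle-like, and 100% lay in a cluster of their class. Whether adult and old cells of the same class cluster together was not tested.

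Alternatives fixed beforehand were at least 1000 genes per cell, at most 5% mitochondrial UMIs, Leiden resolutions 0.5 and 2, 4000 variable genes, clustering each library on its own, doublets kept, CPM minimums of 20 and 200, a list minimum of 200 UMIs, mean CPM over cells, ratios centred on the median gene, thinned cells, and totals without blood-cell genes. Alternatives added after the data were examined were the removal of high doublet scores, cluster 4 counted as CAR-like, ratios without background genes, cluster 7 or cluster 12 alone, and ratios centred within 20 bins of gene length. Software was Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.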

Results

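Transcriptomes of single cells were collected from the long-bone marrow of adult and old mice after most blood-forming cells had been depleted and live cells had been sorted, with 1 library per age group. The comparison asks how the cells that form the marrow niche, the mesenchymal, bone-forming and vascular cells around blood stem cells, differ between the ages. The adult library held 25635 barcodes and 208637421 UMIs, and the old library held 22298 barcodes and 229917243 UMIs. After filtering, 22403 adult cells with a median of 7139 UMIs and 2937 genes, and 18975 old cells with a median of 7736 UMIs and 3062 genes, were compared. RNA of 28052 genes was detected in the adult and 27838 in the old library. Mitochondrial transcripts made up a median of 2.41% of UMIs in adult and 2.34% in old cells. Xist, which is transcribed from the inactive X chromosome, was at 726 CPM in the adult and 711 CPM in the old library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were each at or below 0.178 CPM in both.

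CAR-like cells, the mesenchymal cells that make CXCL12 and stem cell factor, were the main population in both libraries, with 58.1% of adult cells (95% interval 57.5% to 58.8%) and 75.8% of old cells (75.2% to 76.4%), but at Leiden resolution 2 and with 4000 variable genes the old share was the lower (below). Every other named stromal class took a smaller share in the old library. Osteolineage-like cells, the bone-forming lineage, made up 11.98% of adult (11.6% to 12.4%) and 4.50% of old cells (4.20% to 4.80%), a ratio of 0.375. Endothelial-like cells, which line the marrow vessels, made up 7.85% (7.50% to 8.21%) and 2.11% (1.91% to 2.33%), a ratio of 0.269. Chondrocyte-like cells, which make cartilage, numbered 727 in the adult library (3.25%, 3.02% to 3.49%) and 0 of 18975 in the old library, which allows a share of up to 0.0158% by counting error. That limit counts named clusters only, and clusters under 20 cells were joined to others. Of old barcodes, 69 had UMIs of at least 3 chondrocyte markers, 1 of them removed by the filters. Col2a1 was found in 73.0% of old and 73.7% of adult osteolineage-like cells, so old cells of this kind under another name stay possible.

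Pericyte or smooth muscle-like cells made up 2.19% of adult and 1.14% of old cells, a ratio of 0.522. Fibroblast-like cells made up 0.433% and 0.184%, and Schwann-like cells 0.107% and 0.0264%. When shares were taken over the named non-haematopoietic cells, CAR-like cells made up 69.3% of 18808 adult and 90.5% of 15900 old cells. On that denominator, osteolineage-like cells made up 14.3% and 5.36%, and endothelial-like cells 9.35% and 2.52%. Clusters that took no name held 12.6% of adult and 0.943% of old cells. Most of these adult cells were in 1 cluster led by Hs3st5, Wif1 and Alpl, with 2252 adult and 24 old cells. It scored highest for CAR markers (0.704) and next for osteolineage markers (0.529), and the osteolineage marker Alpl was among its 10 leading genes.

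Among blood cells that passed the depletion, plasma cell-like cells, which secrete antibody, differed most. None was found in the adult library (0 of 22403 cells, which allows up to 0.0134%), whereas 1275 made up 6.72% of the old library (6.37% to 7.08%). Erythroid-like cells made up 1.15% of adult (1.016% to 1.3001%) and 5.602% of old cells (5.28% to 5.94%), 4.86 times the adult share. Neutrophil lineage-like cells took 0.170% and 0.791%, T or NK-like cells 0.0312% and 0.195%, and B lineage-like cells 0.138% and 0.0738%. Megakaryocyte-like cells, the source of platelets, took 1.995% (1.82% to 2.19%) and 1.88% (1.69% to 2.08%). Plasma cell-like and old erythroid-like cells were deep, with medians of 34037 and 40939 UMIs. Removing the highest 10% of doublet scores left the plasma cell-like share and the erythroid-like ratio within their intervals, but the scores come from Scrublet, which did not work here, so doublets are not excluded. Old erythroid-like cells had a mean of 181 Igkc UMIs against 17.2 in old CAR-like cells, and Jchain in 30.2% against 17.4% of cells. Mixing with plasma cell-like cells was not tested. The depletion and the sort act on these shares, and neither their yield nor the marrow's cell numbers are given in the sources used here.

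**Figure D1:**
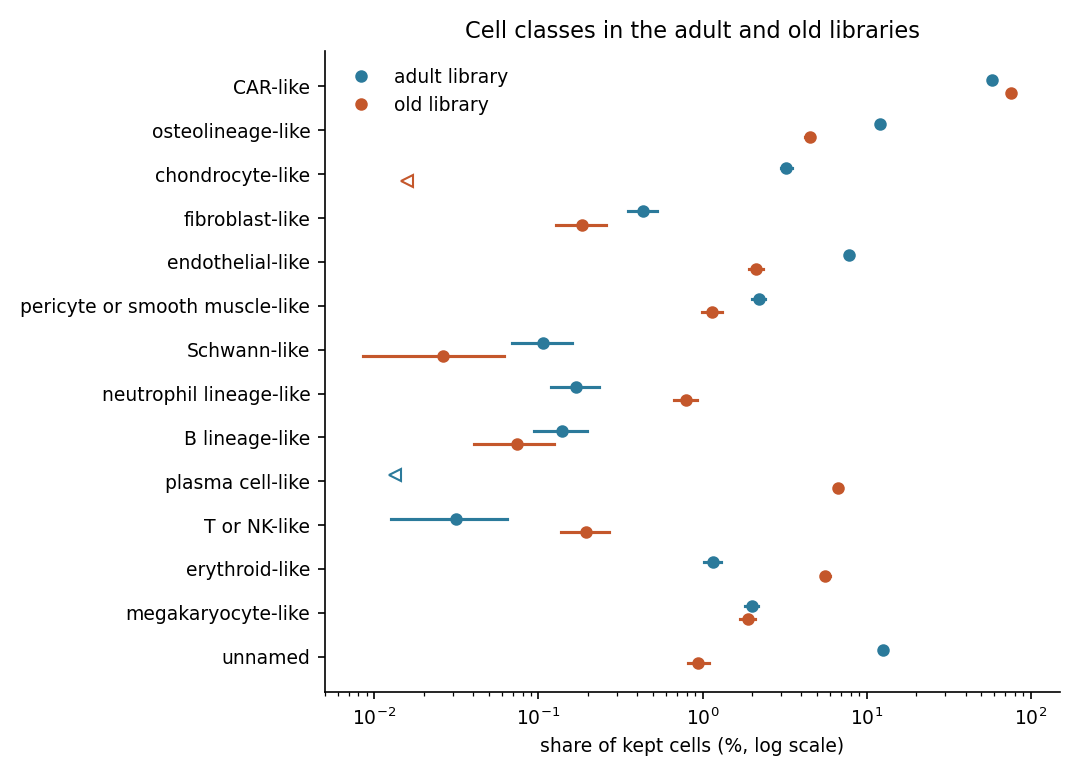
Percent of kept cells in each named class (log axis) in the adult and the old library, as points with 95% Clopper-Pearson bars and open triangles for the upper limit where 0 cells were found. Plasma cell-like, erythroid-like and, in most but not all clusterings, CAR-like shares were higher in the old library, and osteolineage-like, endothelial-like and chondrocyte-like shares were lower.

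The clusters behind several shares were nearly separate by library. Of the adult CAR-like cells, 95.9% were in 3 clusters (0, 3 and 5) with 62 old cells, and of the old ones 96.7% were in 5 clusters (1, 2, 6, 8 and 11) with 110 adult cells. Ratios within CAR-like and osteolineage-like cells therefore also compare clusters, and genes that set those clusters apart are among them. Adult osteolineage-like cells were mainly in cluster 9 (46.9%, 0 old cells) and cluster 10 (43.3%), and old ones in cluster 12 (81.6%) and cluster 34 (9.50%). Cluster 9 scored 0.684 for osteolineage and 0.666 for CAR markers, and cluster 34 scored 0.569 and 0.623, so their leading genes decided the name. Those of cluster 9 include Col1a1 and Bglap, which were also found in 91.3% and 71.8% of adult megakaryocyte-like cells. Free RNA may therefore enter its name, which was not tested. Endothelial-like cells of both ages were mainly in cluster 7, with 62.7% of adult and 92.3% of old ones. Cluster 18, led by the sinusoidal gene Stab2, held 30.9% of adult and 4.24% of old endothelial-like cells. All 3 chondrocyte-like clusters (17, 33 and 41) held adult cells only, and all 3 plasma cell-like clusters (13, 22 and 25) held old cells only. Cluster 17, with 80.7% of the chondrocyte-like cells, scored 0.669 for chondrocyte and 0.69 for osteolineage markers, and its leading genes decided the name. Pericyte or smooth muscle-like cells formed 1 cluster, 14.

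The higher CAR-like share turned to a ratio of 0.911 at Leiden resolution 2 and to 0.915 with 4000 variable genes, and old clusters of 1968 and 1418 cells in the first and of 4569 cells in the second took no name there. The osteolineage-like ratio moved to 0.834 at resolution 0.5 and 0.744 with each library clustered on its own, the chondrocyte-like adult share was 1.31% at either other resolution, and with at least 1000 genes per cell the megakaryocyte-like ratio was 2.79 and the erythroid-like ratio 8.07.

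In CAR-like cells, interferon response, antigen presentation and, by their median, complement genes were higher in the old library and immediate early and matrix genes were lower, while Cxcl12 and Kitl were close. The complement list did not stand apart under every alternative (below). C3, the central component of complement, was at 83.5 CPM in adult and 805 CPM in old cells, 9.64-fold higher (log2 3.27, interval 3.24 to 3.30). Cxcl13 (ENSMUSG00000023078), a chemokine that attracts B cells, was at 9.18 and 143 CPM, 15.6-fold higher (log2 3.96, 3.87 to 4.06). Tnfsf11 (ENSMUSG00000022015), which encodes RANKL, the cytokine that drives osteoclast formation, was 4.50-fold lower, at 880.2 CPM in adult and 196 CPM in old cells (log2 −2.17, −2.19 to −2.15). Ptn, which encodes the growth factor pleiotrophin, was 5.31-fold lower (359 and 67.5 CPM). Cxcl12 was at 8709 and 7828 CPM (log2 −0.15) and Kitl, which encodes stem cell factor, at 3869 and 4068 CPM (log2 0.07).

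Of 4187 genes past the minimum in CAR-like cells, 116 were at least 2-fold higher and 73 at least 2-fold lower in the old library. These rest on 100979842 adult and 114606184 old UMIs from 13027 and 14389 cells of median depth 7005 and 7257 UMIs. Among genes of at least 100 CPM that the naming rule admits, the 10 with the highest ratios also held Grm7, a glutamate receptor (log2 3.93), Hdac9, a histone deacetylase (3.72), Enpp2, which makes lysophosphatidic acid (3.39), Gas7 (3.24), Fndc1 (3.11), Efemp1, an extracellular matrix protein (2.90), and Kcnab1 (2.68). Slpi, a protease inhibitor, had the highest of these ratios (4.03), with UMIs in 86.4% of old CAR-like cells but also in 90.5% of old megakaryocyte-like cells, at the level of free RNA. The lowest ratios among the same genes also held Fgf13 (−2.03), Col3a1 (256 and 64.2 CPM), the vitamin D receptor Vdr (−1.94), the BMP target Id3 (−1.89) and Kcne4 (−1.84). Bglap (−3.90), Col1a1 (−2.84) and Col11a1 (−2.15), made by bone and cartilage cells, were among the lowest too. Free RNA can give over 30% of their UMIs, and Col1a1 was found in 97.1% of adult CAR-like and 91.3% of adult megakaryocyte-like cells, of median depth 1602 UMIs. Several named genes also lead clusters held by 1 library, such as Tnfsf11, Ptn and Kcne4 in adult cluster 0, Grm7 and Efemp1 in old cluster 1, C3 and Hdac9 in old cluster 2, and Cxcl13 in old cluster 6. Without genes whose background can give that much, 105 were higher and 64 lower.

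Lepr, the leptin receptor that marks CAR cells, was at log2 0.24, and the transcription factors that maintain them, Ebf3 and Foxc1, were at 0.19 and 0.33. Cxcl14 (0.66) and Nrp1 (0.44) lay farthest above among the identity list, which split evenly (9 of 18 members higher, median 0.08) but had 2 members at least 2-fold lower and none as far above, with a mean of −0.135. Among niche factors, 10 of 28 were higher and 18 lower (median −0.08), a median within the random lists. Their mean was −0.415, with 4 members at least 2-fold lower and 1 at least 2-fold higher. The vascular growth factor Angpt1 (−0.96), Igf1 (−1.47), Bmp4 (−0.93), the adhesion molecule Vcam1 (−0.81) and Il7, which supports B cell precursors (−0.60), were lower, and Csf1 was at −0.09. Adipogenic genes had a median of −0.09 (13 higher, 14 lower of 27), with lower Adipoq (−0.60), Cebpb (−1.40) and Lpl (−1.28). Lpl and Vcam1 are members of the identity list too. Small ratios changed sign with the processing: centred by gene length, Cxcl12 was at 0.04, Kitl at −0.07 and Csf1 at 0.05, and with 4000 variable genes Kitl and Ebf3 were each at −0.02.

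The immune lists stood above the random lists in CAR-like cells. Of 31 interferon response genes, 29 were higher in the old library (median 0.48), with Oas1a at 1.92 and Ifi27l2a at 1.57. Antigen presentation genes were higher in 19 of 21 cases (median 0.51), among them the class I activator Nlrc5 (1.28) and the class II gene H2-Ab1 (1.63). Complement and acute phase genes were higher in 13 of 20 (median 0.25), with Saa3 (4.38) and Cfb (1.79) beside C3. Of these 20 genes, 6 were at least 2-fold higher and 3 at least 2-fold lower. Inflammatory cytokines went both ways (13 higher and 11 lower of 24, median 0.09), and Cxcl5, partly open to free RNA, was at 3.54. RNA of abundant blood cells was higher in 15 of 17 genes (median 0.93), and Igkc, an immunoglobulin light chain, was found in 0.169% of adult and 100% of old CAR-like cells.

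Early response and matrix lists stood below. All 26 immediate early genes, which stress and tissue digestion also induce, were lower in the old library (median −0.72), with Nr4a1 at −1.70, Ier5 at −1.65 and Fos at −1.35. Collagens and matrix genes were lower in 20 of 30 (median −0.39), among them Col12a1 (−1.41), and matrix remodelling enzymes in 16 of 25 (median −0.36), among them Adamts1 (−1.28) and Adamts4 (−1.14). Senescence and growth arrest genes were lower in 14 of 21 (median −0.31), with Gadd45g at −1.42 and Btg2 at −1.13. Cell cycle genes were lower in 24 of 28 (median −0.39), among them the spindle gene Tpx2 (7.39 and 3.00 CPM), but with each library clustered on its own the median was 0.25. Cluster 23, led by Cenpf and Top2a, held 209 adult and 42 old CAR-like cells (1.60% and 0.292%). Whether it carries the cell cycle difference was not tested. The IGF system was lower in 11 of 13 (median −0.29), with Irs2 at −0.67, and oxidative phosphorylation genes in 34 of 35 (median −0.26), with Uqcrb at −0.58 and Cycs at −0.52. Under some alternatives, 5 of these lists came to lie within the random lists: senescence and cell cycle with each cell weighted alike, senescence and IGF with each library clustered on its own, IGF also with at least 1000 genes per cell or with cluster 4 counted as CAR-like, oxidative phosphorylation without background genes, and complement without blood-cell genes or with at least 200 UMIs per member.

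Osteogenic genes (median −0.49, 13 of 24 lower) and endothelial vascular genes (median −0.75, 22 of 29 lower) also stood below in CAR-like cells. Cdh5 (−3.71) and Kdr (−2.90) were found there at the level of free RNA, and without members that background can give, the medians were 0.09 and 0.11. Of the remaining lists, all within the random lists, TGF-beta and BMP signalling had a median of −0.04, with Id2 at −2.53 and Id1 at −1.64, and Wnt and Notch signalling −0.10, with Wnt11 at −2.54 and Wnt4 at −1.04. Glycolysis and hypoxia genes had −0.07 (Hk2 −1.56), heat shock genes −0.14 (Hspa8 −0.72), the unfolded protein response −0.07 (Dnajb11 −0.34), ribosomal proteins −0.08 (Rps20 −0.26), and scavenging and lysosome genes −0.10 (Cd63 −0.52). Antioxidant genes had a median of 0.08 (Mt2 2.43), and mitochondrially encoded transcripts 0.08 (mt-Atp8 0.35).

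Gene length went with the ratio in all 4 stromal classes compared. With genes split into 4 equal groups by length, the shortest had a median log2 ratio of −0.25 in CAR-like cells and the longest 0.18, a gap of 0.43, and the gap was 0.92 in osteolineage-like, 0.23 in endothelial-like and 0.63 in pericyte or smooth muscle-like cells. With ratios centred within bins of length, the oxidative phosphorylation (−0.02), IGF (−0.07) and senescence (−0.10) lists no longer stood apart in CAR-like cells, and the inflammatory (0.31), antioxidant (0.23), mitochondrially encoded (0.34) and ribosomal (0.18) lists stood above.

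**Figure D2:**
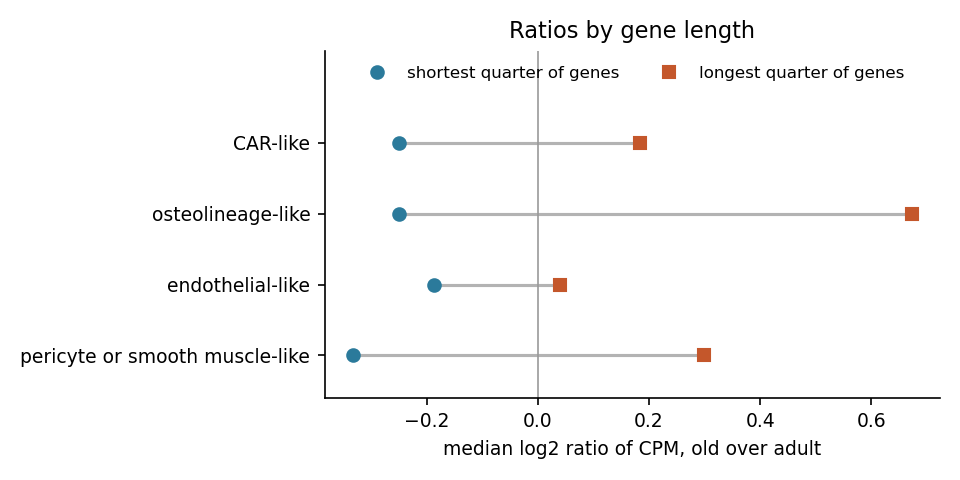
Median log2 ratio of old over adult CPM (horizontal axis) of the shortest and the longest of 4 equal groups of genes, by gene span, in 4 classes. Long genes had a higher median than short genes in every class, with the widest gap, 0.92, in osteolineage-like cells.

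Osteolineage-like cells of the old library had less Col1a1 and Col1a2 mRNA, for the major bone collagen, and more Spp1, Mmp13 and Postn mRNA, though Spp1 and Mmp13 did not hold within 1 cluster (below). Col1a1 was at 73835 CPM in adult and 14800.0 CPM in old cells (log2 −2.32, −2.33 to −2.31) and Col1a2 at 52596 and 13071 CPM (−2.01). Spp1 (ENSMUSG00000029304), which encodes osteopontin, was at 3769 and 41278 CPM (log2 3.45, 3.44 to 3.46). Mmp13, a collagenase, was at 529 and 4786 CPM (3.18), and Postn, which encodes periostin, at 161 and 1643 CPM (3.35).

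Of 3818 genes past the minimum there, 470 were at least 2-fold higher and 166 at least 2-fold lower in the old library, over 41560344 adult and 10859751 old UMIs. The median of all genes was itself at 0.147, so list medians are read against the matched random lists. Among genes that the naming rule admits, the highest ratios also held Rgs20 (3.76), the phagocytic receptor Megf10 (3.54), Btla (3.48), Angpt4 (3.23), Tmem86a (3.19), the integrin Itgb5 (3.18) and the receptor phosphatase Ptprz1 (3.03). The lowest ratios among the same genes were those of Ptn (−3.70), Adarb2 (−3.62), Cthrc1, a matrix protein of active osteoblasts (−3.29), Col3a1 (−3.13), the proteoglycan Lum (−2.67), Cpz (−2.64), Bglap3 (−2.58), Cgref1 (−2.58), Serpinf1 (−2.56) and the BMP inhibitor Bambi (−2.56). Spp1, Postn, Ptprz1 and Mmp13 lead cluster 12, which holds most of the old cells, and Col1a1, Cthrc1, Serpinf1, Cpz and Cgref1 lead adult cluster 9, so these ratios compare the clusters. In cluster 12 alone, with 118 adult and 696 old cells, 104 genes were higher and 78 lower, and Spp1 (−0.13), Mmp13 (−0.27) and Cgref1 (0.20) turned direction.

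Complement and acute phase genes stood above the random lists in osteolineage-like cells, with 13 of 15 higher (median 0.91), among them Saa3 (2.95) and Steap4 (2.05). Interferon response genes were higher in 26 of 29 (median 0.63), with Bst2 at 1.42, and antigen presentation genes in 16 of 18 (median 0.61), with Nlrc5 at 1.38 and H2-Q4 at 1.31. In cluster 12 alone, the interferon median of 0.17 lay within the random lists. Immediate early genes were lower in 22 of 26 (median −0.67), with Atf3 at −2.11 and Nr4a2 at −1.77. Collagens and matrix genes stood below (17 of 30 lower, median −0.33), as did niche factors (17 of 26, −0.29, Igf1 −2.09), adipogenic genes (14 of 21, −0.30, Fabp4 −3.61), senescence genes (−0.13), antioxidant genes (−0.08), cell cycle genes (−0.00), oxidative phosphorylation genes (33 of 35 lower, −0.38, Ndufa1 −1.38) and ribosomal proteins (38 of 40 lower, −0.26, Rplp0 −0.66). Endothelial vascular genes (−1.90) and blood-cell RNA (−1.04, with a mean of 0.868) were also below, both of them genes of other cell types. Osteogenic genes (0.20, 13 of 24 higher, Mepe 3.21) and matrix remodelling enzymes (0.30, 16 of 23 higher, Timp3 2.82) lay within the random lists.

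With each cell weighted alike, none of the 3 immune lists stood above the random lists, and with each library clustered on its own, the niche (0.65), collagen (0.32), antioxidant (0.26), cell cycle (1.53) and blood-cell RNA (3.92) lists turned direction. Centring by gene length took the oxidative phosphorylation, ribosomal, senescence and antioxidant lists inside the random lists, put the matrix remodelling (0.39) and mitochondrially encoded (0.44) lists above them, and brought the count of higher genes to 249, or 54.2% of called genes against 73.9%, whereas that count was 772 at Leiden resolution 0.5.

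Relative to the class total, endothelial-like cells of the old library had more mRNA of arterial and antigen-presenting genes and less of sinusoidal genes. The share of this class was smaller in the old library, so fewer sinusoidal cells would by themselves raise the arterial ratios. These ratios do not show more arterial cells. Stab2 (ENSMUSG00000035459), a scavenger receptor of marrow sinusoids, was at 1127 CPM in adult and 215 CPM in old cells (log2 −2.39, −2.52 to −2.26). Cd74 (ENSMUSG00000024610), the chaperone of class II molecules, was at 2.14 and 202 CPM (log2 6.56, 5.98 to 7.21). All 11 arterial genes were at least 2-fold higher (median 1.71), with Mecom at 184 and 1073 CPM (2.55), Sema3g at 74.5 and 406 CPM (2.45) and Gja5, a gap junction gene of arteries, at 12.2 and 48.6 CPM (1.99). Of 9 sinusoidal genes, 7 were at least 2-fold lower (median −1.36), with Mrc1 at −1.96, Gpm6a at −1.84 and Stab1 at −1.36.

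After thinning to 2000 UMIs, 46.7% of 1503 adult (44.2% to 49.3%) and 11.8% of 338 old endothelial-like cells (8.59% to 15.8%) had a Stab2 UMI, and Sema3g was found in 12.97% and 50.3% (unthinned 21.8% and 65.1%, and 0.353% and 0.417% of CAR-like cells). The thinning left out 255 adult and 63 old cells. Unthinned, Stab2 was found in 54.3% and 18.7% of endothelial-like cells of median depth 5318.5 and 4306 UMIs, and in 4.65% and 0.403% of CAR-like cells of median depth 7005 and 7257 UMIs. Flt4, a receptor of sinusoidal endothelium, was at log2 −1.09, the leukocyte adhesion genes Sele and Vcam1 at −2.69 and −1.24, Emcn at −0.63 and the junction gene Cdh5 at −0.32. Kitl (0.66) and Cxcl12 (0.32) were higher.

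Of 4626 genes past the minimum in endothelial-like cells, 244 were at least 2-fold higher and 151 at least 2-fold lower, over 11708956 adult and 2327177 old UMIs from 1758 and 401 cells. Among genes that the naming rule admits, the highest ratios also held Grm7 (4.78), St8sia6 (3.30), Efhd1 (3.27), Nebl (3.13), Stmn2 (3.02), Tgfb2 (2.68) and Lrrc3b (2.58), with Slpi (5.46) and C3 (3.22), of which free RNA can give over 30%. The lowest among the same genes held Ptn (−3.24), Ston2 (−3.10), Il13ra2 (−2.82), the adhesion gene Selp (−2.75) and Wdr17 (−2.35), with Bglap2 (−5.59), Bglap (−4.92), Col1a1 (−3.06) and Tnfsf11 (−2.48), likewise open to free RNA. Without such genes, 213 were higher and 129 lower.

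Antigen presentation genes were higher in 20 of 20 cases in endothelial-like cells (median 1.07, 12 of them 2-fold), with the class II genes H2-Aa (5.25), H2-Eb1 (4.87) and H2-Ab1 (4.28) farthest. Interferon response genes were higher in 29 of 29 (median 0.53), with Ifit3 at 1.40, and complement genes in 10 of 13 (0.50), with C4b at 1.26. Niche factors stood above by their median (0.16, 15 of 26 higher, Jag2 2.22), but their mean was −0.011 and with each cell weighted alike the median was −0.09. Collagens and matrix genes were lower in 20 of 29 (−0.44), matrix remodelling enzymes in 19 of 24 (−0.28, Adamts5 −2.32), the IGF system in 10 of 11 (−0.33, Igfbp2 −4.97) and osteogenic genes in 16 of 23 (−0.79, and 0.21 without members that background can give). Immediate early genes (−0.32, Fos −0.92), ribosomal proteins (−0.29, 39 of 40 lower) and heat shock genes (−0.22) were below the random lists, and none of these 3 was once ratios were centred by gene length. Without genes that background can give, the collagen, matrix remodelling and heat shock lists lay within the random lists, as did the complement, ribosomal and heat shock lists with each cell weighted alike, the niche list with at least 200 UMIs per member and the IGF list with each library clustered on its own. Endothelial vascular genes lay within them (0.09, 17 of 30 higher, Edn1 2.62).

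Because Stab2-led cluster 18 was mostly adult, cluster 7 was also compared alone, as an alternative chosen after the values were seen. There the sinusoidal median was −1.03, the arterial median 1.32 and the antigen presentation median 1.09. Cluster 7 scored for both subtypes (sinusoidal 0.634, arterial 0.85), so a different mix of them within it is not excluded.

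**Figure D3:**
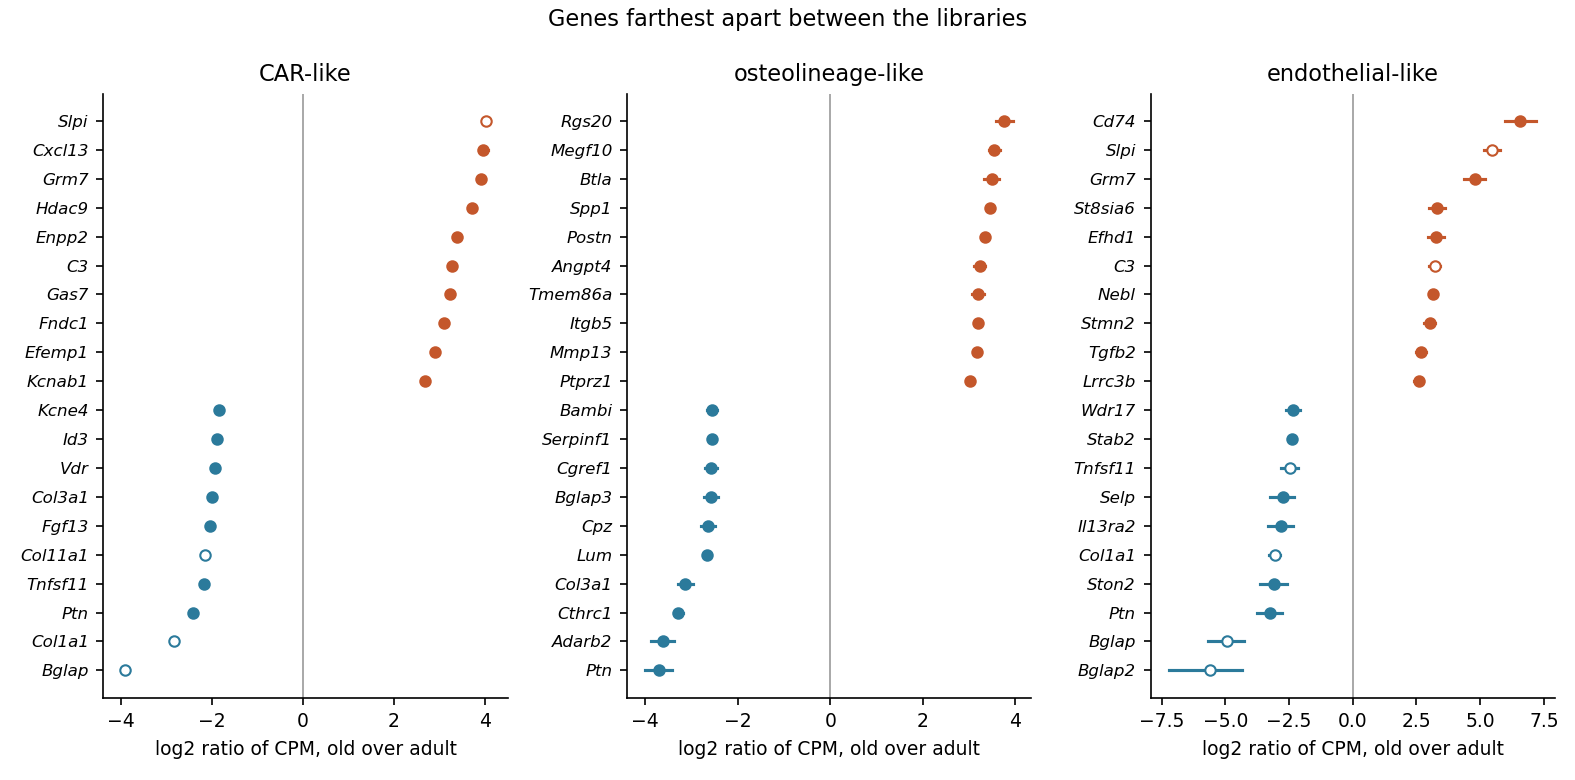
Log2 ratio of old over adult CPM (horizontal axis) of the 10 highest and 10 lowest genes that the naming rule admits in CAR-like, osteolineage-like and endothelial-like cells, with 95% counting intervals as bars and open circles where background can give over 30% of the UMIs. Among the genes drawn, Cd74 has the highest ratio in endothelial-like cells and Spp1 is among the highest in osteolineage-like cells.

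In pericyte or smooth muscle-like cells, which wrap the vessels, the immediate early, collagen and matrix, and TGF-beta and BMP signalling lists stood below the random lists. All 26 immediate early genes were lower (median −0.78), with Klf4 at 379 and 108 CPM (log2 −1.81), and collagens and matrix genes were lower in 24 of 28 (median −0.77), with Col12a1 at −2.70 and Fn1 at −2.30. TGF-beta and BMP signalling stood below as a whole (median −0.44, 16 of 25 lower), with Tgfb2 at −1.81, Id1 at −1.48 and Id3 at −1.31.

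Of 4358 genes past the minimum there, 143 were at least 2-fold higher and 104 at least 2-fold lower, over 3845967 adult and 1476992 old UMIs from 491 and 217 cells. Among genes of at least 100 CPM that the naming rule admits, the highest were Slpi (6.26), Frmd5 (4.72) and C3 (3.48), and the lowest Col11a1 (−4.08), Bglap (−3.44) and Col1a1 (−3.03), of which all but Frmd5 are open to free RNA. Matrix remodelling enzymes (−0.60, 20 of 22 lower, Plat −3.81), niche factors (−0.44, 17 of 21 lower, Ptn −3.46), senescence genes (−0.54, Gadd45b −2.18), osteogenic genes (−0.82) and oxidative phosphorylation genes (−0.32) also stood below. Complement genes (0.35, 8 of 11 higher, C4b 1.56), antigen presentation genes (0.36, 13 of 15 higher, Nlrc5 1.66) and blood-cell RNA (1.85) stood above, and interferon response genes did not (0.07, 16 of 27 higher), although centred by gene length their median of 0.27 did. With each cell thinned to 2000 UMIs, 85 genes were higher and 176 lower, and centring by gene length brought the oxidative phosphorylation median to 0.02, put mitochondrially encoded transcripts (0.52) above the random lists and put CAR cell identity (−0.25) and adipogenic genes (−0.16) below them. Without genes that background can give, the niche, osteogenic and antigen presentation lists lay within the random lists, as did antigen presentation with each cell weighted alike or at least 200 UMIs per member, complement with at least 1000 genes per cell, and both with each library clustered on its own.

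**Figure D4:**
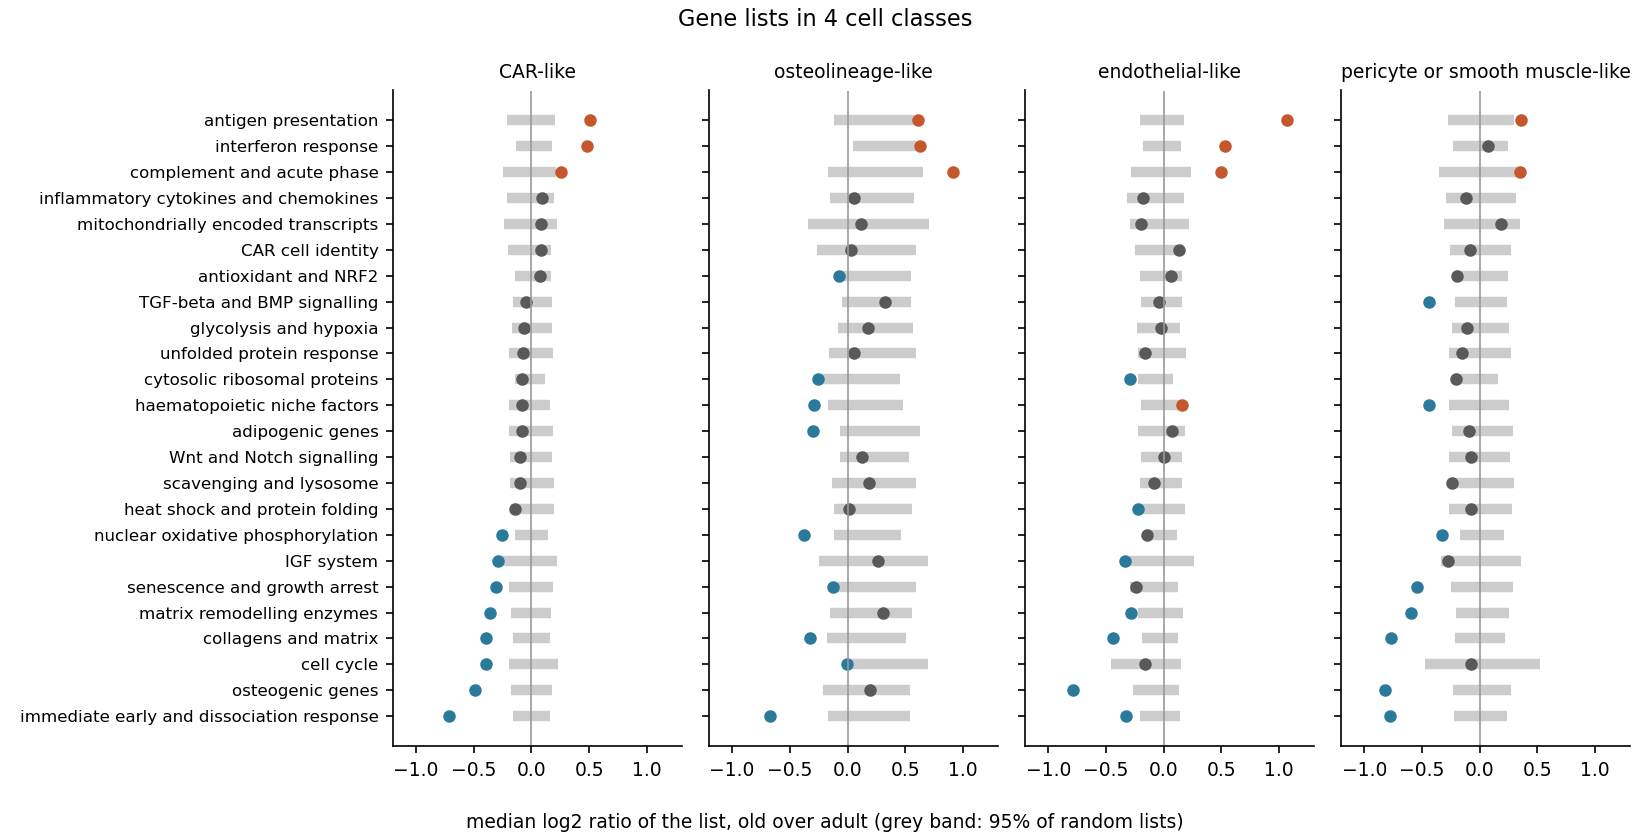
Median log2 ratio of old over adult CPM (horizontal axis) of gene lists in 4 classes, with a grey band for 95% of matched random lists and orange or blue points for medians above or below it. The blood-cell RNA, endothelial vascular, endothelial subtype and sex-linked lists are not drawn. Antigen presentation lies above the band and immediate early genes lie below it in all 4 classes, the first of these not under every alternative in osteolineage-like and pericyte or smooth muscle-like cells, and the second not in endothelial-like cells once centred by gene length.

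In erythroid-like cells, among genes that the naming rule admits, Fabp5, a fatty acid carrier (log2 3.65), and the amino acid transporter Slc38a1 (2.48) were the highest in the old library, with Slpi (5.40). The lowest were the skeletal genes Col11a1 (−6.22), Col2a1 (−5.61) and Bglap (−5.55), which bone and cartilage cells make. Old erythroid-like cells had a median of 40939 UMIs and adult ones 8357.5, but Bglap was lower per cell too, with 1.70 UMIs in adult and 0.131 in old cells, as was Col2a1, with 2.90 and 0.214. Cluster 16 held 54.4% of old and 10.1% of adult erythroid-like cells, and clusters 24 and 26 held 14.6% and 13.7% of old and 30.2% and 31.01% of adult ones, so these ratios also compare clusters. Of 4228 genes, 908 were at least 2-fold higher and 676 at least 2-fold lower. Relative to the class total, genes of CAR cells were lower as well. The greater depth of the old cells lowers the CPM of a gene whose UMIs per cell stay the same. How much of the fall in CAR genes this depth gives was not tested, so a fall per cell is not shown by their ratios. All 18 identity genes were at least 2-fold lower (median −2.40), as were 19 of 21 niche factors, and the other 2 were at least 2-fold higher. Cluster 24 scored 0.592 for erythroid and 0.591 for CAR markers, so RNA of CAR cells among the adult erythroid-like cells may enter these counts. In megakaryocyte-like cells, 298 of 2952 genes were higher and 227 lower. The level of free RNA was itself read from megakaryocyte-like and erythroid-like cells, so it cannot tell free RNA from the cells' own in these classes. In other classes it is too high for genes that both of these make. Among genes that the naming rule admits, the highest were Gda (3.32), the glutathione transferase Gstt1 (2.89) and Mir142hg (2.67), and the lowest the bone genes Col1a1 (−6.69), Bglap (−6.57) and Bglap2 (−5.99). With each cell weighted alike, Col1a1 was at −4.33 and Bglap at −5.40 in megakaryocyte-like cells, and Col11a1 at −4.58, Col2a1 at −5.26 and Bglap at −4.93 in erythroid-like cells.

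All of these differences are between 1 adult and 1 old library, so the intervals cover counting error and not the spread between mice, and library preparation cannot be told apart from age.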

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

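The tests of free immunoglobulin RNA, of blood-cell removal, of removal by the cell filters from removed barcodes, of loss after RNA release, of free RNA and of nuclear RNA in CAR-like cells were chosen only after the result was seen.

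Plasma cell-like cells were found in the old library alone, and 1 heavy-chain V gene dominated them. Counts of V genes alone do not show that cells share 1 antibody. Of 1224 such cells with a heavy-chain V gene call, 74.9% (917 cells, 72.4% to 77.3%) had Ighv1-54 as their most counted V gene, the next being Ighv14-1 with 8.01%. Immunoglobulin genes lead these clusters and are among the markers that named them. A higher immunoglobulin share than in other cells was therefore set by the selection, but its size was not. These genes gave a median of 47.2% of UMIs in these cells and 0.339% in old CAR-like cells, a ratio of 139. Free immunoglobulin RNA at the level of old CAR-like cells is argued against as the source, and free RNA spread unevenly over droplets was not tested. A poorer removal of all blood cells from the old preparation may contribute and stays open. The megakaryocyte-like share had an old over adult ratio of 0.943 (0.818 to 1.09). It was 2.79 with at least 1000 genes per cell, a minimum that most of these shallow cells do not reach. Erythroid-like (4.86), neutrophil lineage-like (4.66) and T or NK-like cells (6.24) went with a poorer removal, whereas B lineage-like cells (0.533, from 31 and 14 cells) did not. Expansion of 1 clone with age or in a single mouse is a hypothesis that 1 library cannot test.

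Chondrocyte-like and endothelial-like cells were scarcer in the old library. Removal by the cell filters as the whole cause is argued against: with all removed old barcodes that had a UMI of any such marker counted as such cells (525 endothelial, 274 chondrocyte), and no removed adult ones, the old over adult ratio of the share of barcodes reached 0.606 (0.559 to 0.656) for endothelial-like and 0.433 (0.376 to 0.499) for chondrocyte-like cells. Barcodes with at least 3 markers, a test set beforehand, had ratios of 0.263 and 0.0220 over all deposited barcodes, but free RNA adds to such barcodes, so these decide nothing. Loss of these cells after their RNA had entered the suspension stays open. Free UMIs of 18 such markers per CAR-like cell had a low median ratio of 0.231 (quartiles 0.140 to 0.348). But cells were sorted before they were loaded, so RNA set free before the sort need not reach the droplets. The 18 markers were also picked as free RNA on adult values alone, so this test cannot decide. A difference in dissection, in release from the bone by digestion or in sorting may give the same values, as may fewer such cells in old bone, and these stay open with 1 library per age.

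In CAR-like cells, 189 genes were at least 2-fold apart. Free RNA as the whole cause is argued against, since 89.4% of them (169) remain without genes that background can give, and gene length as the whole cause is argued against, since 84.1% (159) stay 2-fold apart once ratios are centred by length. A length trend, as from another share of unspliced RNA, stays open as a part, with a gap of 0.43 (0.40 to 0.46) between the longest and the shortest genes, between the bounds set beforehand. The nuclear RNAs Malat1 (log2 −0.26) and Neat1 (0.25) went opposite ways. Their level of free RNA cannot be read here. In the old library that of Neat1 (3.14 UMIs per cell) exceeded the whole CAR-like mean (2.70), and that of Malat1 (164) the endothelial-like mean (147). A shift shared between cell types in 1 library may also contribute, since 47 of the genes that could be read in pericyte or smooth muscle-like cells had a median of 0.90 (resampled range 0.64 to 0.99, quartiles 0.11 to 1.33, 37 in the same direction) there, against 1.37 in CAR-like cells, 24 in endothelial-like cells had 0.69 (quartiles −0.22 to 1.25, 16 in the same direction, 2 at least 2-fold opposite) against 1.23, and 60 in osteolineage-like cells had 1.85 (49 in the same direction, 5 at least 2-fold opposite) against 1.42, or 1.40 (43 of 54) without genes that background can give in CAR-like cells. Such a shift can come from age or from preparation, which cannot be told apart, and CAR-like and osteolineage-like ratios also compare clusters.

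Some genes were at least 2-fold apart in opposite directions in a pair of classes, and these differences between classes were not tested. Osteolineage-like cells were left out of this search because different clusters hold them in the libraries, which is as true of the CAR-like cells kept in it, so their ratios below also compare clusters. Map1b, a microtubule protein, was at log2 2.11 in CAR-like and −1.25 in endothelial-like cells (difference 3.36). Pcsk5, a proprotein convertase, was at −1.03 and 2.29 (difference −3.32). Between endothelial-like and pericyte or smooth muscle-like cells, Tgfb2 was at 2.68 and −1.81 (4.49), Klf4 at 1.05 and −1.81 (2.86), the elastin gene Eln at 1.51 and −1.33 (2.84), and the netrin receptor Unc5b at 1.31 and −1.23 (2.54). Between the same classes, Nrg3 was at 1.48 and −1.48 (2.95), the endothelin receptor Ednrb at −1.39 and 2.93 (−4.32), and Map1b at −1.25 and 1.32 (−2.57).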

How the results depend on the processing

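The removal of high doublet scores, the count of cluster 4 as CAR-like, cluster 7 or 12 alone, the genes without background and the centring by gene length were alternatives chosen only after the data were examined. Across all alternatives, 213 of the main values stayed, shares within their interval and counts within 1.5 times, while 57 moved and 2 reversed. Among list medians and single genes 1434 stayed, 669 moved and 23 reversed. Of 940 alternative values of the 69 named genes at least 2-fold apart, 937 kept their direction and 928 stayed 2-fold apart. Most of these genes were picked for extreme ratios in the same counts, and some alternatives leave a class unchanged. This tally therefore says little about how firm the difference between the libraries is. Keeping doublets moved nothing, since 0 were called, and was not run. No paired analysis was possible because each group has 1 library. Except where a minimum of CPM or UMIs admits more or fewer genes, or clusters are left out, the cause of these moves was not tested.

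The CAR-like ratio (1.304) was 1.21 at 5% mitochondrial UMIs, 1.18 at resolution 0.5, 0.911 at resolution 2, 0.915 with 4000 variable genes, 1.06 with libraries clustered apart, 1.21 without high doublet scores and 1.11 with cluster 4. The osteolineage-like ratio (0.375) was 0.834 at resolution 0.5 and 0.744 with libraries clustered apart. The adult chondrocyte-like share (3.25%) was 3.53% at 5% mitochondrial UMIs, 1.31% at resolution 0.5 and 2, 2.90% with 4000 variable genes and 2.91% with libraries clustered apart. The megakaryocyte-like ratio (0.943) was 2.79 with at least 1000 genes and 0.799 at resolution 0.5. The erythroid-like ratio (4.86) was 8.07 with at least 1000 genes, 6.01 at 5% mitochondrial UMIs, 5.99 with 4000 variable genes and 3.97 with libraries clustered apart. The old plasma cell-like share (6.72%) was 7.22% with at least 1000 genes, 7.29% at 5% mitochondrial UMIs, 7.18% at resolution 0.5, 4.92% at resolution 2, 5.24% with 4000 variable genes and 5.84% with libraries clustered apart.

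At a minimum of 20 CPM, the genes higher and lower in the old library were 208 and 138 in CAR-like, 841 and 289 in osteolineage-like, 378 and 282 in endothelial-like, and 291 and 245 in pericyte or smooth muscle-like cells. At 200 CPM they were 38 and 29, 162 and 81, 80 and 43, and 44 and 30. Osteolineage-like cells had 772 higher genes at resolution 0.5, 249 centred by length, and 104 higher and 78 lower in cluster 12 alone. Thinned pericyte or smooth muscle-like cells had 85 higher and 176 lower. The percentage of called genes that were higher went from 57.9% to 32.6% in them and from 61.8% to 49.8% in endothelial-like cells on thinning, and in osteolineage-like cells from 73.9% to 62.5% centred on the median gene and 54.2% by length. Thinning left 459 adult and 192 old pericyte or smooth muscle-like cells, and 1503 and 338 endothelial-like cells. With fewer UMIs in the old library, the minimum of 50 UMIs asks for a higher CPM of genes higher there. Genes past the minimum fell from 4358 to 2904 in pericyte or smooth muscle-like cells, so these drops cannot be read as a change of direction.

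The lists above the random lists were 8 by length and 2 without blood-cell genes in CAR-like cells (4), and 5 by length, 0 by mean CPM of cells and 6 with libraries clustered apart in osteolineage-like cells (3). In pericyte or smooth muscle-like cells (3) they were 5 by length and 1 with libraries clustered apart. Those below were 7 by length and 6 with libraries clustered apart in osteolineage-like cells (11), and 5 by length and 4 without background genes in endothelial-like cells (8).

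Reversed medians in CAR-like cells were osteogenic 0.094 and endothelial vascular 0.11 without background genes, and cell cycle 0.25 with libraries clustered apart. In osteolineage-like cells, with libraries clustered apart, they were niche 0.65, collagens 0.32, antioxidant 0.26, cell cycle 1.53 and blood-cell RNA 3.92. Also reversed there were antioxidant genes (0.053 by length), cell cycle (0.11 with 200 UMIs) and, in cluster 12 alone, endothelial vascular genes (0.067), blood-cell RNA (0.50), Spp1 (−0.13), Mmp13 (−0.27) and Cgref1 (0.20). In endothelial-like cells, niche factors were −0.089 by mean CPM of cells and osteogenic genes 0.21 without background genes. Oxidative phosphorylation in pericyte or smooth muscle-like cells was 0.017 by length. In CAR-like cells, Kitl was −0.025 and Ebf3 −0.021 with 4000 variable genes, and Cxcl12 was 0.035, Kitl −0.067 and Csf1 0.054 by length.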

Other observations

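The test of the interferon-high cells was chosen before its result was seen, and the V gene pairing below was looked at only after the data were examined.

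The old plasma cell-like cells held a recurrent pair of heavy-chain and light-chain V genes. Across 36 heavy-chain V genes, Ighv1-54 led and Ighv1-15 made up 3.68%. Among light chains, Igkv12-44 was the most counted in 63.9% of 1259 cells and Iglv1 in 20.97%. In the cells called for them, these 2 genes gave medians of 73.5% and 57.3% of light-chain V UMIs. Ighv1-54 gave a median of 100% of heavy-chain V UMIs in its cells. Barcodes thus held UMIs of more than 1 light-chain V gene, so the light-chain groups need not be separate kinds of cell. Of 916 cells with Ighv1-54 and a light-chain call, 85.9% (787) had Igkv12-44, whereas 1.64% (5 of 305) of the cells with another heavy-chain V gene did. The isotype Ighg2b was the most counted in 99.3% of the cells with Ighv1-54 and in 76.2% of the others. In the adult library Ighv1-54 had 0 UMIs, and in the old library it had 118623, and 13.4% of old CAR-like cells carried at least 1 of them as free RNA.

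A group of CAR-like cells in both libraries, with 214 adult and 281 old cells, was led by interferon targets such as Cxcl10, Cxcl9 and Ifit3. That a small group of interferon-high cells carries the higher interferon list in old CAR-like cells was tested as a hypothesis and is argued against. Without the cluster, the list's median was 0.58 against 0.48 with it, and 30 of 31 genes were higher in the old library. Within the cluster alone the median was −0.08, at the 20.97 percentile of random lists, and antigen presentation genes had a median of 0.17 (11 of 15 higher), at the 93.7 percentile.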
